A study of Danio rerio with 30 samples.

How the data were processed

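RNA-seq was deposited for 12 libraries of mCherry-positive cells, which fall into 4 groups of 3 by genotype (isl1a mutant or sibling) and treatment (homeostasis or 3 h after neomycin). Group and replicate number were taken from the sample titles. The series' design text calls the samples biological triplicates, and the labels do not say whether they came from separate clutches, so p-values measure the spread between these samples. Per the labels' protocols, larvae were dissociated with trypsin, cells were sorted into Trizol, and libraries were made from total RNA with the SMART-Seq v4 kit. That kit does not mark strand, so reads of overlapping or antisense genes cannot be separated. The 18 ATAC-seq samples were not analysed here.

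The authors deposited 1 table of whole-number read counts per Ensembl gene, with 1 column per library and no normalization. STAR 2.7.3a, bcl2fastq 2.18, RSEM, Bowtie2 and the genome build danRer11 are named, per the submitters' processing notes, which give no role or order. The annotation release, the strand setting and any filter are not given in the sources used here. The table has 32520 genes and 4 further entries that name no gene, for ambiguous, multimapping, unassigned and unmapped reads. These took 28.2% to 35.2% of the reads of a library and were left out of library sizes and tests. The remaining counts came to 23918226 to 30354161 per library. Reads that map to several places were not counted to genes, so near-identical paralogs and multigene families may be undercounted and their values are uncertain. Counts are of PCR-amplified reads without molecular identifiers, so the 95% intervals given for ISL1, from exact Poisson bounds on the mutant counts, cover counting error only.

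Symbols came from a name table and were found for 29201 gene IDs. It often gives human-style symbols, and 1719 symbols are shared by 6136 IDs, so a gene with a shared symbol is printed with its Ensembl ID. isl1b has its own entry, and the ID named ISL1 was taken as isl1a. No genome of the build came with the data. Of the gene IDs, 54.7% could be placed on a chromosome through a gene table of another assembly. No coordinates are therefore printed, and a planned test for genotype calls clustering on the chromosome of isl1a was void, because 68.9% of tested genes had a position and 80% were needed.

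Genes were kept by edgeR's filterByExpr over the 4 groups, which left 22000. Libraries were scaled by TMM, and all 12 entered 1 model with a mean per group, so that the groups share an estimate of the spread (common dispersion 0.104, a biological coefficient of variation of 32.3%). Contrasts were mutant against sibling in homeostasis and at 3 h, 3 h against homeostasis in siblings and in mutants, and the difference between both responses. Each was tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes. Every adjusted p of a gene is from that test unless another is named, and a gene is said to have changed, risen or fallen at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are counts divided by the TMM-scaled library size, and values on a log scale used a prior count of 2. Principal components were computed from log2 CPM. Pairs of libraries within a group were compared by a chi-square test over genes with at least 20 counts, and all differed by more than counting noise, which does not exclude technical duplicates.

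The design, the tests, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The lists cover neuromast cell types, signalling pathways, cell cycle, stress and ribosome programmes, and markers of 10 kinds of other cells that a sort could hold. Of 730 list names, 552 matched a symbol exactly, 149 matched by stem, which takes in paralogs, and 29 did not match. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each was tested again with an estimated correlation and with fry. Camera asks whether a list moved more than the other genes, and fry whether its genes moved one way on balance. A further 9 lists were chosen after the data had been seen and were adjusted among themselves.

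The text takes the genes it names from this rule. The isl family is named throughout. For each comparison it gives up to 10 genes higher and 10 lower with the smallest adjusted p, among those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, an informative symbol and, except for the interaction, CPM that did not overlap between the groups. For each list it gives up to 4 called members with the smallest adjusted p, or up to 2 of the most abundant members where none was called. Many genes that the rule gives are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

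Replicate numbers are shared by all groups. Whether they pair libraries was checked by correlating the deviations of same-numbered libraries from their group means. Mutants and siblings at 3 h were paired by this check, with correlations of 0.302, 0.46 and 0.192. The labels do not say what the numbers mark. For that comparison, values with the replicate number as a block are printed where they differ.

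Alternatives were the block, DESeq2's size factors or upper-quartile scaling in edgeR, DESeq2, voom with quality weights, other filters, a robust fit, fits of the 6 libraries compared, each library left out in turn, stricter thresholds, and fits without the 993 genes placed on the chromosome of isl1a or without 288 genes of the lists of other cells, ribosomal proteins and mitochondrially encoded genes. Overlaps of called genes were set beside the number expected for independent lists, and, where comparisons shared libraries, beside 20 simulations of unchanged groups. Tests were first tried on simulated counts for 21609 genes, 200 of them changed. For mutants against siblings in homeostasis, 11% of 2-fold and 78% of 4-fold changes were recovered. For 3 h against homeostasis in mutants, 17% and 75% were. A spiked list of 30 genes had a camera adjusted p of 5.46e-12. Genes were drawn independently, so 0 calls among 29 other lists cannot gauge false calls. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.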

Results

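Expression was measured by RNA-seq in mCherry-positive cells sorted from zebrafish larvae of the she:mCherry reporter line at 5 days post fertilization. The larvae were mutants for isl1a, which encodes a LIM homeodomain transcription factor (allele psi97), or their siblings. They were taken either in homeostasis or 3 h after a 30 min exposure to 300 uM neomycin, an aminoglycoside antibiotic that kills the mechanosensory hair cells of the lateral line. Each of the 4 groups held 3 libraries with between 23918226 and 30354161 counts in genes, and 25403 to 27260 genes had at least 1 count in a library. A further 18 ATAC-seq samples in 6 groups, which add a time point 1 h after neomycin, were not analysed here. The title of the series places the work in lateral line regeneration and asks what isl1a does at its onset and its end. The comparisons below therefore address how mutants and siblings differ before and after hair cell loss, how each responds to neomycin, and whether the responses differ.

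The mutated gene itself followed the labels in all 12 libraries. ISL1 (ENSDARG00000004023, taken here as isl1a) had 164 ± 49.5 CPM in siblings in homeostasis (SD, n = 3, as for all CPM values after ±) and 193 ± 84.6 CPM in siblings at 3 h. The 3 mutant libraries in homeostasis held 0, 1 and 0 counts, against 3351, 5607 and 5189 in their siblings. Over each group, that is 1 count in mutants and a sibling level 13900 times higher, with a 95% counting interval from 2490 to 548000. At 3 h the mutant libraries held 6, 35 and 0 counts and their siblings 3996, 6634 and 4591, a ratio of 345 with an interval from 254 to 481. Most of the 41 mutant counts at 3 h came from replicate 2, and a call of higher ISL1 in mutants after neomycin (adjusted p = 0.046) was lost without that library (0.31), among others. The paralog isl1b had at most 9 counts in any library and was not tested. ISL2 (ENSDARG00000003971) was at 16.5, 15, 9.54 and 6.52 CPM in siblings and mutants in homeostasis and siblings and mutants at 3 h. It fell after neomycin in siblings (log2 fold change −0.79, adjusted p = 0.033) and in mutants (−1.22, adjusted p = 0.0046). The sibling call was lost without sibling replicate 1 at 3 h (0.062) or sibling replicates 2 or 3 in homeostasis (0.082 and 0.12). A second ISL2 gene (ENSDARG00000053499) was at 0.412, 1.51, 0.837 and 0.439 CPM in the same order and was not called between genotypes (adjusted p = 0.094 in homeostasis and 0.31 at 3 h). It fell in mutants after neomycin (−1.78, adjusted p = 0.047), a call lost (0.06 to 0.17) without any mutant replicate at 3 h, or mutant replicates 2 or 3 or any sibling replicate in homeostasis.

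Libraries separated by both treatment and genotype. The first principal component of log2 CPM held 37.9% of the variance and ordered the groups from siblings in homeostasis, through mutants in homeostasis and siblings at 3 h, to mutants at 3 h. Sibling replicate 2 at 3 h stood apart from the other 11 libraries on the second component (20.4% of the variance), at −129. Its mean correlation with its own group was 0.925, the lowest of the 12. That library also held 2620 CPM of apoa2, a plasma apolipoprotein gene expressed in liver, against at most 1140 in any other. All pairs of libraries within a group differed by more than counting noise, so none was treated as a library deposited again. Amplified reads of technical duplicates can differ by as much, and the 12 were counted as separate samples because the labels list them so.

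**Figure D1:**
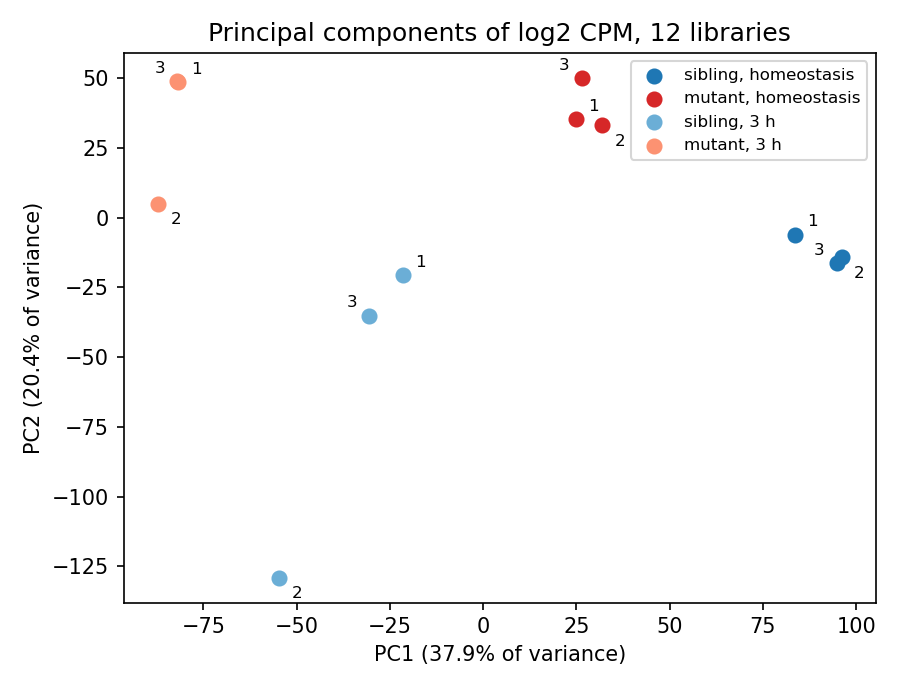
First 2 principal components of log2 CPM over the 12 libraries, coloured by group and numbered by replicate. Sibling replicate 2 at 3 h lies at −129 on the second component, far from replicates 1 and 3 of its group.

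The first comparison asked how neuromast cells of isl1a mutants differ from those of siblings before any damage. As lists, mature hair cell genes were lower in mutants, and genes of the AP-1 and inflammation programmes, of red blood cells and of skeletal muscle were higher. OSBPL1A, which encodes an oxysterol-binding protein and was listed with the mature hair cell genes, fell from 445 ± 42.7 to 178 ± 19.9 CPM (log2 fold change −1.32 ± 0.18 SE, adjusted p = 0.0022). FOSL1, which encodes an AP-1 subunit, rose from 3.16 ± 0.907 to 35.2 ± 5.6 CPM (3.48 ± 0.25, adjusted p = 4.2e-05). The haemoglobin gene hbae5 rose from 0.547 ± 0.127 to 44.5 ± 11.4 CPM (6.33 ± 0.38, adjusted p = 1.1e-05).

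Of 46 tested mature hair cell genes, 8 fell, none rose and 38 were not called in mutants in homeostasis; adjusted over the list alone, 30 fell. The list had a median log2 fold change of −0.98 and was lower than the other genes (camera adjusted p = 1.6e-17), a call that held with adjusted p = 0.019 with an estimated correlation. ESPNL (ENSDARG00000078211), an espin-like gene of the stereocilia, fell from 142 ± 17.2 to 54.4 ± 19.1 CPM. OTOF (ENSDARG00000020581), which encodes the otoferlin of the hair cell synapse, fell from 2180 ± 148 to 967 ± 57.1 CPM (−1.17, adjusted p = 0.022). The call of OTOF was lost, with adjusted p between 0.052 and 0.11, without any 1 of the 6 homeostasis libraries. The count of 8 became 2 without any 1 of the 3 mutant libraries or sibling replicate 2 in homeostasis, 4 and 5 without sibling replicates 1 and 3 in homeostasis, and 14 and 29 without sibling replicates 1 and 2 at 3 h.

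Among 28 genes of hair cell progenitors and specification, 4 fell and 1 rose (adjusted over the list alone, 7 and 1), with a median of −0.33. The list was lower (camera adjusted p = 0.0011; adjusted p = 0.44 with an estimated correlation). Without sibling replicate 2 at 3 h, 7 fell, and without sibling replicates 1 and 3 in homeostasis the median was −0.51 and −0.09. None rose without mutant replicates 1 or 3 at 3 h, or any mutant replicate or sibling replicates 1 or 2 in homeostasis. The homeobox genes BARHL1, barhl1a and LHX3 were among those that fell, by 2.1, 1.41 and 1.28 on the log2 scale. The mantle and anteroposterior support cell list moved the other way. It had 3 members that rose, 1 that fell and 12 not called (5 and 1 over the list alone), a median of 0.61 and a camera adjusted p of 2.6e-05 (0.019 with an estimated correlation). PKHD1L1 (ENSDARG00000091116), a large transmembrane protein gene in that list, rose from 54.3 ± 9.62 to 185 ± 50.2 CPM (adjusted p = 0.0046). Without mutant replicate 2 or sibling replicate 2 in homeostasis, 1 member of the mantle list rose, and none fell without any 1 homeostasis library or mutant replicates 1 or 3 at 3 h. The central support cell list had no call among 14 genes, with a median of −0.06, a mean of 0.14 and a test pointing down (adjusted p = 0.97). In the pan-neuromast list 2 of 22 genes fell, both paralogs of PAX2, or 1 without any 1 homeostasis library (2 rose without sibling replicate 2 at 3 h), and the list as a whole stayed near 0 (median 0.04, mean −0.04, adjusted p = 0.87). PAX2 (ENSDARG00000028148) fell from 43.1 ± 10.9 to 17.2 ± 0.296 CPM, adjusted p = 0.0068.

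Of 42 immediate early and AP-1 genes, 11 rose and none fell in mutants in homeostasis (adjusted over the list alone, 19 rose). The median was 0.73 and the camera adjusted p 8.7e-22 (0.019 with an estimated correlation). FOSL2, another AP-1 subunit gene, rose from 11.3 ± 0.981 to 43.4 ± 10.8 CPM, and egr2a, a zinc finger transcription factor gene, from 2.43 ± 0.449 to 15.4 ± 3.93 CPM. Without sibling replicate 2 at 3 h, 20 rose. In the inflammation and Jak-Stat3 list, 10 of 35 genes rose and none fell (14 and 1 over the list alone), with a median of 0.74 and a camera adjusted p of 2.9e-07 (0.019 with an estimated correlation). MMP9 and il6st, the gene of the signal-transducing receptor subunit of the interleukin 6 family, rose by 1.99 and 1.48 on the log2 scale. The cytokine gene lepb went from 0.0107 to 1.69 CPM. The 10 became 4, 6, 5 and 6 without mutant replicate 1 and sibling replicates 1, 2 and 3 in homeostasis. The leukocyte list had a median of 0.17 (adjusted p = 0.73). Heat shock and ribosome biogenesis lists were higher without any called member, with medians of 0.43 and 0.41 and camera adjusted p of 0.00027 and 8.3e-06 (adjusted p = 0.44 and 0.47 with an estimated correlation). Adjusted over the list alone, 6 heat shock genes rose. The heat shock median was 0.18 without sibling replicate 1 and 0.26 without mutant replicate 3 in homeostasis. With sibling replicate 2 at 3 h left out, 3 heat shock and 5 ribosome biogenesis genes rose, and 5 heat shock genes rose without sibling replicate 3 in homeostasis. Notch, Fgf, retinoic acid, G2 and M phase, unfolded protein, p53, ribosomal protein and mitochondrially encoded lists were not called (adjusted p from 0.12 to 0.91). The same held for Wnt and S phase (both 0.066), apart from Notch without sibling replicate 1 (0.043), Wnt without mutant replicate 2 (0.029) and S phase without sibling replicate 3 in homeostasis (0.0013).

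Markers of cells outside the neuromast moved with the same libraries. Of 8 erythrocyte genes, 6 rose (7 over the list alone), with a median of 3.00 and a camera adjusted p of 1.7e-21 (0.015 with an estimated correlation). hbae1.3 rose from 35.2 ± 17.3 to 476 ± 103 CPM, and alas2, the first enzyme of haem synthesis in red cells, from 5.91 ± 1.04 to 65.1 ± 12.7 CPM. Of 25 skeletal muscle genes, 9 rose (18 over the list alone), with a median of 1.83 and a camera adjusted p of 1.6e-17 (0.022 with an estimated correlation). The actin gene actc1b rose from 6.05 ± 1.24 to 61.5 ± 31.6 CPM. The 9 became 3 or 4 without mutant replicates 2 or 3 or sibling replicates 2 or 3 in homeostasis, and 15 without sibling replicate 2 at 3 h. Neuron markers were higher with 1 called member and 4 over the list alone (median 0.75, camera adjusted p = 0.00029; adjusted p = 0.063 with an estimated correlation). Epidermis markers were higher with 1 called member (0.42, camera adjusted p = 0.021; adjusted p = 0.14 with an estimated correlation). Without sibling replicate 2 at 3 h, 3 neuron genes rose, and 5 epidermis genes rose and 2 fell, while no gene of either list rose without mutant replicate 2 or sibling replicates 1 or 2 in homeostasis. The epidermis call was lost without mutant replicate 1 (0.094) or sibling replicate 1 (0.059) in homeostasis. Ionocyte, glia, pigment cell, retina and fibroblast lists were not called (0.1 to 0.89), except ionocyte and fibroblast without sibling replicate 1 (0.014 and 0.043) and glia without mutant replicate 1 (0.038) or sibling replicate 2 (0.0017) in homeostasis.

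In all, 785 of 22000 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 407 higher and 378 lower in mutants. The genes with the smallest adjusted p also included ca4a, SLC16A9 (ENSDARG00000013926), TIMP2 (ENSDARG00000075261), ADM (ENSDARG00000069027) and HSD11B2, which rose by 4.29, 3.92, 3.25, 4.05 and 2.92 on the log2 scale. Those lower in mutants were led by C1QTNF5, from 11.7 ± 3.85 to 2.3 ± 0.315 CPM, and GALNT9, from 76.9 ± 7.61 to 28.7 ± 1 CPM, and included PKLR, the pyruvate kinase gene of liver and red cells (131 ± 51.8 to 4.71 ± 2.99 CPM). Genes named by their rank were required to have the 3 libraries of one genotype above all 3 of the other, which chance alone gives in 10% of genes. The total fell to 296, 350 and 295 (203, 225 and 217 of them higher) without mutant replicates 1, 2 and 3 and to 502, 309 and 413 (339, 185 and 220 higher) without sibling replicates 1, 2 and 3 in homeostasis, so the even split was not stable. It was 2079 (888 higher) without sibling replicate 2 at 3 h, a library outside this contrast that shares its estimate of the spread. Of the 57 calls that the naming rule gives, not all printed here, 39 held in each of the 12 fits that left 1 library out.

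**Figure D2:**
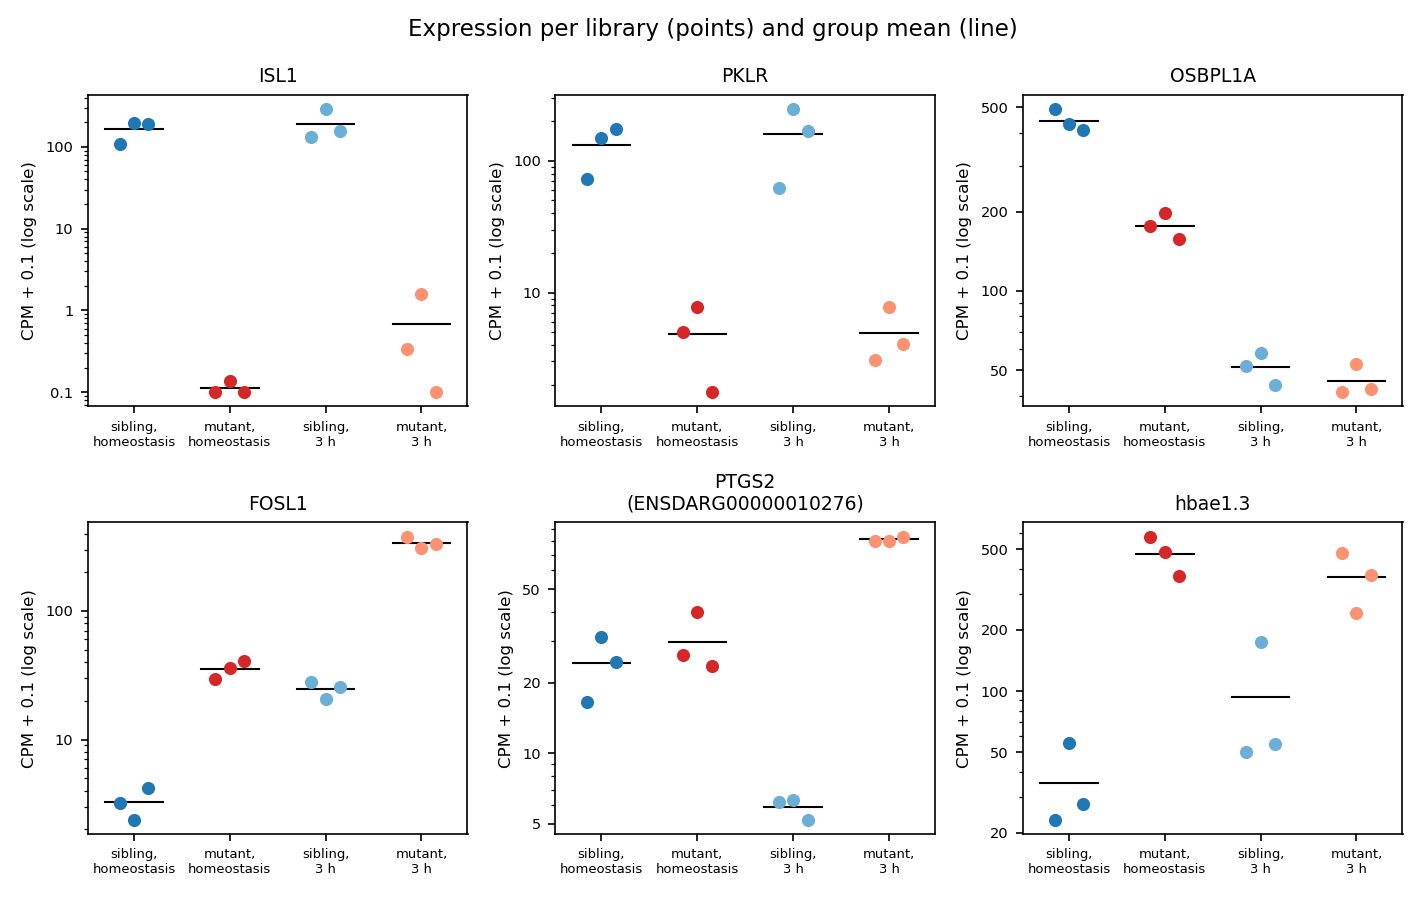
Normalised CPM plus 0.1 for 6 genes on a log scale, with 1 point per library (n = 3 per group) and a line at the group mean. ISL1 and PKLR are low in both mutant groups, OSBPL1A is lower in mutants in homeostasis and in both groups at 3 h, FOSL1 and hbae1.3 are higher in mutants, and PTGS2 is lowest in siblings and highest in mutants at 3 h.

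The second comparison asked how mutants differ from siblings 3 h after hair cell killing. Mutants had more of AP-1 and inflammation transcripts, in list calls that held with an estimated correlation (both 0.017). Heat shock genes as a list were higher, and progenitor, mature hair cell and Fgf pathway lists lower, with the preset correlation only (adjusted p from 0.35 to 0.48 with an estimated correlation). FOSL1 reached 339 ± 35.6 CPM against 24.6 ± 3.77 in siblings (3.78 ± 0.24 SE, adjusted p = 9.1e-06). PLEK2, which encodes a pleckstrin family protein of the actin cytoskeleton, was at 175 ± 27 against 10.5 ± 3.08 CPM (4.05 ± 0.25, adjusted p = 9.1e-06). PTGS2 (ENSDARG00000010276), which encodes a cyclooxygenase of prostaglandin synthesis, was at 81.3 ± 1.93 against 5.8 ± 0.601 CPM (3.81 ± 0.28, adjusted p = 2e-05).

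Of 42 immediate early and AP-1 genes, 24 were higher and 1 lower in mutants at 3 h (26 and 2 over the list alone). The list's median was 1.37 and its camera adjusted p 3.5e-27 (0.017 with an estimated correlation). DUSP5, a phosphatase gene of the ERK pathway, was at 130 ± 19.4 against 8.84 ± 3.11 CPM, and FOSL2 at 106 ± 21 against 19.3 ± 0.329 CPM. None was lower without any mutant replicate or sibling replicate 1 at 3 h or mutant replicate 3 in homeostasis. In the inflammation and Jak-Stat3 list, 13 of 35 genes were higher and 1 lower (16 and 5 over the list alone; median 1.07, camera adjusted p = 1.1e-10, 0.017 with an estimated correlation). SOCS3 (ENSDARG00000025428), the feedback inhibitor of Jak-Stat3 signalling, was at 159 ± 9.39 against 23.4 ± 7.23 CPM, and MMP9 at 81.4 ± 33.4 against 8.57 ± 0.703 CPM. Without sibling replicates 1 and 3 at 3 h, 2 and 3 genes of that list were lower, and none was without any mutant replicate or sibling replicate 2 at 3 h or mutant replicate 1 in homeostasis. Leukocyte markers were lower in the same mutant libraries (median −0.76, camera adjusted p = 0.014; adjusted p = 0.64 with an estimated correlation), with 2 of 27 members called lower, or 5 with the replicate number as a block. The call of the leukocyte list was lost without mutant replicate 3 (0.097) or sibling replicate 2 (0.22) at 3 h, and without the latter the median was −0.25. No leukocyte gene was lower without mutant replicates 1 or 3 or sibling replicate 2 at 3 h, and 1 was without mutant replicate 1 or sibling replicate 2 in homeostasis.

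Among heat shock genes 3 of 23 were higher (5 over the list alone, 7 with the block, 6 without sibling replicate 3 in homeostasis), with a median of 0.32 (camera adjusted p = 0.0016; adjusted p = 0.48 with an estimated correlation). The co-chaperone gene BAG3 was at 18.2 ± 2.97 against 4.95 ± 0.993 CPM (adjusted p = 0.00047). In the unfolded protein and integrated stress response list 4 of 26 were higher (4 higher and 3 lower over the list alone), among them TRIB3 at 260 ± 42.4 against 58.6 ± 9.11 CPM and atf5a (1.98). The median was 0.02 and the list was not called (adjusted p = 0.06), except without mutant replicate 1 at 3 h (0.034), sibling replicate 2 at 3 h (0.0043, with 7 higher) or sibling replicate 1 in homeostasis (0.048). Of 20 p53 target genes 2 were higher, 6 over the list alone and 4 with the block, including GADD45A (ENSDARG00000104571; 1.09, adjusted p = 0.005). The list's camera adjusted p of 0.022 (adjusted p = 0.38 with an estimated correlation) rose to 0.057 and 0.1 without sibling replicates 1 and 3 at 3 h. Without sibling replicate 1 at 3 h, 4 p53 targets were higher.

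The mature hair cell and progenitor lists were lower in mutants at 3 h with the preset correlation only (adjusted p = 0.35 and 0.43 with an estimated correlation). Of 46 mature hair cell genes, 9 were lower and none higher (18 over the list alone), and 14 were lower with the block. The median was −0.74 and the camera adjusted p 2e-04. The 9 became 0 without mutant replicates 1 or 3 at 3 h, 2, 4 and 4 without mutant replicates 1, 2 and 3 in homeostasis, and 4, 2 and 5 without sibling replicates 1, 2 and 3 in homeostasis. Of 28 progenitor and specification genes, 7 were lower (13 over the list alone, 11 with the block), with a median of −0.90 and a camera adjusted p of 0.00053. LHX3 was at 1.41 ± 0.19 against 3.17 ± 0.333 CPM (adjusted p = 0.0066), and BARHL1 at 0.973 ± 0.0832 against 3.22 ± 1.38 CPM. The 7 became 3 without mutant replicates 1 or 3 at 3 h, 4 without mutant replicate 1 in homeostasis and 12 without sibling replicate 1 at 3 h, and the median was −0.46 without sibling replicate 2 at 3 h.

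In the Fgf pathway list 4 of 21 genes were lower and none higher (the same numbers over the list alone), with a median of −0.47. Its camera adjusted p of 0.0499 lay at the threshold (0.057 with the block; adjusted p = 0.48 with an estimated correlation) and was 0.0035 without sibling replicate 2 at 3 h. The call was lost, with adjusted p from 0.052 to 0.39, without mutant replicate 2 or sibling replicates 1 or 3 at 3 h, or any mutant replicate or sibling replicates 2 or 3 in homeostasis. The median was −0.31 without mutant replicate 2 and −0.26 without sibling replicate 1 at 3 h. Without mutant replicates 1 or 3 at 3 h, 1 was lower, and 2 were higher and 2 lower without sibling replicate 1 at 3 h. The ligand gene FGF10 (ENSDARG00000030932) was at 64.6 against 141 CPM (−1.13, adjusted p = 0.001). The Wnt target SP5 was at 4.46 ± 0.465 against 18.8 ± 4.07 CPM, and the retinaldehyde dehydrogenase gene ALDH1A3 at 20.8 against 48.3 CPM, in lists with 1 higher and 3 lower each that were not called (0.27 for Wnt, 0.41 for retinoic acid). With the block, 2 Wnt genes were higher and 5 lower. In each list 2 were higher without sibling replicate 2 and none without mutant replicates 1 or 2 at 3 h. Without mutant replicates 2 or 3 at 3 h only 1 Wnt gene was lower, and only 1 retinoic acid gene was lower without mutant replicates 1 or 3 or sibling replicate 1 at 3 h, any mutant replicate or sibling replicates 1 or 2 in homeostasis. Mantle genes were again higher (4 of 16 higher, 1 lower, median 0.61, camera adjusted p = 2e-04; adjusted p = 0.056 with an estimated correlation). They included PKHD1L1 (ENSDARG00000091116) at 375 ± 77 against 73.3 ± 21.1 CPM and ovgp1 at 91.4 against 27.8 CPM. Leaving out any 1 mutant library at 3 h left 2 higher and none lower, and none was lower without sibling replicates 1 or 3 at 3 h. Among central support cell genes 1 was higher and 3 lower (1 and 5 over the list alone, 1 and 6 with the block; list adjusted p = 0.15). None of them was lower without mutant replicates 1 or 3 at 3 h, and without mutant replicate 2 at 3 h 5 were lower and the list was called (0.017). In the pan-neuromast list 1 of 22 was higher, the cadherin gene cdh1 (738 ± 46.5 against 317 ± 31.5 CPM), and 4 were lower (list adjusted p = 0.21), or 1 without mutant replicates 1 or 3 at 3 h; without sibling replicate 2 at 3 h, 3 were higher.

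Erythrocyte genes were higher in mutants at 3 h as well (3 of 8 called, 6 over the list alone, median 1.73, camera adjusted p = 1.6e-06; adjusted p = 0.2 with an estimated correlation), or 5 of 8 without mutant or sibling replicate 2 at 3 h, and the median was 1.06 without mutant replicate 1 at 3 h. So were muscle genes (3 of 25, 5 over the list alone and 5 with the block; median 0.94, camera adjusted p = 2e-04; adjusted p = 0.38 with an estimated correlation), or 9 of 25 without sibling replicate 2 at 3 h, and the median was 0.41 without mutant replicate 3 at 3 h. Ribosomal protein genes were lower without any called member (median −0.46, camera adjusted p = 3e-05; adjusted p = 0.66 with an estimated correlation), a shift that rested on sibling replicate 2 at 3 h: without it the median was −0.09 and the adjusted p 0.23. G2 and M phase genes were lower with 1 called member (−0.51, camera adjusted p = 0.015; adjusted p = 0.58 with an estimated correlation), but not without mutant replicate 3 (0.083) or sibling replicate 2 (0.14, median −0.24) at 3 h. Without sibling replicates 1 and 3 at 3 h, 2 and 3 of them were lower, and none was without any 1 mutant library or sibling library in homeostasis. In the retina and lens list 2 of 7 genes were lower (−1.0, camera adjusted p = 0.029; adjusted p = 0.2 with an estimated correlation), a call lost without mutant replicate 2 at 3 h (0.062). The median was −2.15 without mutant replicate 3 at 3 h, and 1 gene was lower without mutant replicates 2 or 3 or sibling replicate 1 at 3 h, or any mutant replicate or sibling replicates 1 or 2 in homeostasis. The other lists were not called. Neuron markers became so with the block (0.045, 4 higher against 2 without it) and without mutant replicate 1 at 3 h (0.031), and 5 were higher without sibling replicate 2 at 3 h. Ribosome biogenesis genes were called without sibling replicate 2 at 3 h (0.0043), as were fibroblast markers (0.018, 4 lower), and mitochondrially encoded genes without sibling replicate 1 at 3 h (0.049).

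At 3 h, 2151 genes differed between mutants and siblings, 1077 higher and 1074 lower. Further genes with the smallest adjusted p were F2RL1 (ENSDARG00000077540), a protease-activated receptor gene, at 138 ± 13.7 against 26.7 ± 1.09 CPM, EFHD2, lsp1b and tmem154 (2.40, 2.64 and 3.44). Genes lower in mutants included C1QTNF5 (1.79 ± 0.117 against 27.5 ± 3.98 CPM), the transcription factor genes pitx1 and hoxa13b (−1.59 and −3.30) and ZNF385B (−2.0). The total fell to 943 and 896 (605 and 593 of them higher) without mutant replicates 1 and 3 at 3 h, and 658 were lower without mutant replicate 1 in homeostasis, so this even split was not stable either. The total was 2964 (1603 higher) without sibling replicate 2 at 3 h, with 1845 of the 2151 among them. Of the 85 calls that the naming rule gives, 50 held in each of the 12 fits that left 1 library out. The median over all tested genes was −0.14 in this comparison and 0.01 in homeostasis.

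The genotype differences before and after neomycin overlapped. Of the genes higher in mutants, 241 were called in both comparisons, against 19.9 expected for independent lists, and of those lower 168 were, against 18.5; 7 were called in opposite directions. Across genes the log2 fold changes had a Pearson correlation of 0.547 and a Spearman correlation of 0.481, where genes are not independent replicates.

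The third comparison asked what neomycin does to sibling cells within 3 h. Of the mature hair cell genes 36 of 46 fell, and of the ribosome biogenesis genes 38 of 39 rose (list adjusted p = 0.018 and 0.15 with an estimated correlation). OTOF (ENSDARG00000020581) fell from 2180 ± 148 to 216 ± 82.4 CPM (−3.34 ± 0.27 SE, adjusted p = 9.1e-06), and SLC17A8, the vesicular glutamate transporter gene of hair cells, from 411 ± 94.5 to 37.2 ± 7.54 CPM (−3.47 ± 0.26, adjusted p = 7.2e-06). BOP1, a ribosome biogenesis factor gene, rose from 20.8 ± 3.78 to 87 ± 14.7 CPM (2.06 ± 0.2, adjusted p = 2.1e-05). The complement gene c7b rose from 0.31 ± 0.254 to 31.8 ± 10.8 CPM (6.66 ± 0.5, adjusted p = 6.9e-06).

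Of 46 mature hair cell genes, 36 fell and none rose (39 over the list alone). The median was −2.1 and the camera adjusted p 4.5e-31 (0.018 with an estimated correlation). The progenitor and specification list went both ways, with 2 members higher and 7 lower (4 and 7 over the list alone). SOX4 (ENSDARG00000004588) rose from 50.5 to 207 CPM (2.04), while gfi1aa, barhl1a and LHX3 fell by 2.87, 2.64 and 2.36 on the log2 scale. Its median was 0.11, its mean −0.17 and its test pointed down (adjusted p = 0.22, or 0.012 without sibling replicate 2 at 3 h). Without sibling replicate 3 at 3 h, 5 rose, and 1 rose without sibling replicate 2 at 3 h or sibling replicate 1 in homeostasis. Central support cell genes had 1 member higher and 6 lower (2 and 7 over the list alone), with SOST and LFNG falling by 1.53 and 1.23 on the log2 scale. Of them 2 were higher without sibling replicate 1 and none without sibling replicate 2 at 3 h or any sibling replicate in homeostasis. The list was called only without sibling replicate 2 at 3 h (0.045) or sibling replicate 1 in homeostasis (0.0087) and otherwise had an adjusted p of 0.11. Of 28 Notch pathway genes 4 fell, including jag2a (132 ± 38.3 to 33.5 ± 7.43 CPM) and HEY1 (193 ± 74.5 to 72.7 ± 8.02 CPM). The list had an adjusted p of 0.07. It was called without sibling replicate 2 at 3 h (9 lower, 0.045) or sibling replicate 1 in homeostasis (7 lower, 0.00032). In the Fgf pathway 8 of 21 fell (9 lower and 1 higher over the list alone; median −0.45, camera adjusted p = 0.01; adjusted p = 0.51 with an estimated correlation). ETV4, an Fgf-responsive transcription factor gene, fell from 144 ± 33.6 to 38.8 ± 13.2 CPM. The 8 became 3, 3 and 4 without sibling replicate 3 at 3 h and sibling replicates 2 and 3 in homeostasis. Wnt pathway genes split into 6 higher and 4 lower and were not called (0.23), with 3 and 2 left without sibling replicate 2 and 5 and 2 without sibling replicate 3 in homeostasis. TNFRSF19 rose by 1.09 and dkk2 and lgr6 fell by 1.86 and 1.68 on the log2 scale. Mantle, pan-neuromast, retinoic acid, S phase and G2 and M phase lists were not called.

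Of 39 ribosome biogenesis genes, 38 rose and none fell (all 39 over the list alone; median 1.52, camera adjusted p = 9.1e-30; adjusted p = 0.15 with an estimated correlation). tsr1, a factor of the small subunit, rose from 53.4 ± 4.71 to 157 ± 8.5 CPM. Of 72 ribosomal protein genes, 70 rose and 1 fell (71 and 1 over the list alone; median 1.02, camera adjusted p = 1.3e-16; adjusted p = 0.57 with an estimated correlation). RPS3A rose from 264 ± 34 to 503 ± 98.6 CPM. The 70 became 36 and 25 without sibling replicates 1 and 2 in homeostasis, and without sibling replicate 2 at 3 h 58 rose with a median of 0.58. Of 23 heat shock genes 9 rose and 1 fell (12 and 1 over the list alone; median 0.95, camera adjusted p = 0.00014; adjusted p = 0.51 with an estimated correlation), or 4 rose without sibling replicate 1 in homeostasis. The mitochondrial chaperonin gene HSPD1 rose from 62.3 ± 16.9 to 228 ± 18.4 CPM. Of 42 AP-1 genes 12 rose and 1 fell (13 and 1 over the list alone; median 0.35, camera adjusted p = 0.00027; adjusted p = 0.51 with an estimated correlation), with egr4 and FOSL1 rising by 6.41 and 2.96 on the log2 scale. Without sibling replicate 2 at 3 h, 3 fell, none fell without sibling replicates 1 or 2 in homeostasis, and the median was 0.54 without sibling replicate 3 at 3 h and 0.62 without sibling replicate 1 in homeostasis. Inflammation genes split into 7 higher and 2 lower without a list call (0.35), with cxcl8a higher (3.06) and PTGS2 (ENSDARG00000010276) and mmp13b lower (−2.05 and −3.83). Only 4 were higher without mutant replicate 1 or sibling replicates 1 or 2 in homeostasis, or sibling replicates 1 or 2 at 3 h. Unfolded protein and p53 lists were not called (0.93 and 0.29), with 5 p53 targets higher and 2 or 3 in each fit that left out a mutant or a sibling homeostasis library.

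Leukocyte markers were higher at 3 h in siblings. Of 27, 21 rose (22 over the list alone; median 2.1, camera adjusted p = 1.4e-09; adjusted p = 0.51 with an estimated correlation), and 19 did with a median of 1.65 without sibling replicate 2 at 3 h. The myeloid transcription factor gene SPI1 rose from 5.06 ± 0.584 to 32.1 ± 22.8 CPM, and cd74a, of antigen presentation, from 4.7 ± 0.97 to 72.6 ± 73 CPM. Mitochondrially encoded genes were higher with 4 called of 13 (10 over the list alone; median 0.68, camera adjusted p = 0.0067; adjusted p = 0.57 with an estimated correlation). The call was lost without sibling replicate 2 at 3 h (0.061, median 0.31), and the 4 became 8 without sibling replicate 1 at 3 h and 0 to 2 without sibling replicates 2 or 3 at 3 h, sibling replicates 1 or 2 in homeostasis, mutant replicate 3 at 3 h or any mutant replicate in homeostasis. Erythrocyte and muscle lists were not called (0.11 and 0.086), except muscle without sibling replicate 1 at 3 h (0.03) or in homeostasis (0.041) and erythrocytes without sibling replicate 2 in homeostasis (0.038). Retina genes had a median of −0.02, a mean of 1.53 and 1 called member, or 2 without sibling replicates 1 or 2 at 3 h or 3 in homeostasis. The epidermis list was not called (0.36). Of its 20 genes 5 rose and 2 fell, with icn rising by 1.85 on the log2 scale and krt5, an epidermal keratin gene, falling from 1360 to 549 CPM. The 5 became 1 to 3 without any 1 library except mutant or sibling replicate 2 at 3 h, and the 2 became 1 without mutant replicate 2 or sibling replicates 1 or 3 at 3 h, or sibling replicates 2 or 3 in homeostasis. In all, 4831 genes passed, 2464 higher and 2367 lower. The total was 3060 (1324 higher) without sibling replicate 2 in homeostasis (1640 rose without replicate 3 there), and 5035 (2080 higher) without sibling replicate 2 at 3 h, of which 3967 were among the 4831.

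The fourth comparison made the same contrast in mutants. There 31 of 46 mature hair cell genes fell, and 38 of 39 ribosome biogenesis, 11 of 23 heat shock and 18 of 42 AP-1 genes rose. Of these lists the hair cell list kept its call with an estimated correlation (0.017, against 0.12, 0.44 and 0.12). SLC17A8 fell from 189 ± 23.8 to 20.4 ± 5.01 CPM (−3.21 ± 0.26 SE, adjusted p = 1.9e-05), and OTOF (ENSDARG00000020581) from 967 ± 57.1 to 137 ± 17.7 CPM. FOSL1 rose from 35.2 ± 5.6 to 339 ± 35.6 CPM (3.27 ± 0.24, adjusted p = 1.3e-05), and c7b from 3.27 ± 0.404 to 298 ± 103 CPM. IRAK3, a negative regulator of Toll-like receptor signalling, rose from 4.19 ± 0.452 to 34.6 ± 2.11 CPM (3.04 ± 0.2, adjusted p = 1.2e-05).

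Of 46 mature hair cell genes, 31 fell and none rose in mutants (34 over the list alone; median −1.96, camera adjusted p = 1.1e-26, 0.017 with an estimated correlation). Progenitor genes were lower with 1 member higher and 7 lower (median −0.23, camera adjusted p = 0.023; adjusted p = 0.66 with an estimated correlation), a call lost without mutant replicate 1 at 3 h (0.13, median −0.09). The median was −0.6 without mutant replicate 2 at 3 h and −0.41 without mutant replicate 1 in homeostasis. In the central support cell list 7 of 14 fell (−0.89, camera adjusted p = 0.001; adjusted p = 0.51 with an estimated correlation), or 4 without mutant replicates 1 or 3 at 3 h or mutant replicate 2 in homeostasis. Of 28 Notch genes 8 fell (−0.56, camera adjusted p = 0.0022; adjusted p = 0.51 with an estimated correlation), including jag2a (−1.80) and HEY1 (−1.60). The 8 became 3 without mutant replicates 1 or 3 at 3 h or mutant replicate 2 in homeostasis, and 5 without mutant replicate 2 at 3 h or replicate 1 in homeostasis. In the Fgf list 10 of 21 fell (12 over the list alone; −0.75, camera adjusted p = 2.6e-05; adjusted p = 0.25 with an estimated correlation), including ETV4 (175 ± 23.9 to 59.5 ± 8.61 CPM) and SPRY2 (−0.94). Wnt genes split into 3 higher and 6 lower (0.56), with dkk2 falling from 97 ± 21 to 15.6 ± 4.53 CPM. None or 1 was higher without mutant replicates 2 or 3 at 3 h or mutant replicates 1 or 2 in homeostasis.

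Of 39 ribosome biogenesis genes, 38 rose in mutants (39 over the list alone; median 1.29, camera adjusted p = 5.5e-27; adjusted p = 0.12 with an estimated correlation). Ribosomal protein genes were higher with none called higher and 1 lower (0.49, camera adjusted p = 1.4e-07; adjusted p = 0.78 with an estimated correlation), and 50 rose without sibling replicate 2 at 3 h. Of 42 AP-1 genes 18 rose (22 higher and 1 lower over the list alone; 0.86, camera adjusted p = 9.6e-13; adjusted p = 0.12 with an estimated correlation), or 11 without mutant replicate 2 in homeostasis. DUSP5 rose from 9.89 ± 1.15 to 130 ± 19.4 CPM. In the inflammation list 8 of 35 rose (0.35, camera adjusted p = 0.00091; adjusted p = 0.12 with an estimated correlation), including il11b (3.72) and PTGS2 (ENSDARG00000010276), from 29.7 ± 8.72 to 81.3 ± 1.93 CPM. The 8 became 3 without mutant replicate 1 at 3 h or mutant replicates 2 or 3 in homeostasis, and 5 without mutant replicate 3 at 3 h. Of 23 heat shock genes 11 rose (12 over the list alone; 0.70, camera adjusted p = 3.4e-06; adjusted p = 0.44 with an estimated correlation), including HSPA4 (ENSDARG00000004754), from 113 ± 11.6 to 354 ± 25.3 CPM. The 11 became 7, 6, 5, 4 and 7 without mutant replicates 2 and 3 at 3 h and mutant replicates 1, 2 and 3 in homeostasis. The p53 list had 4 of 20 higher (0.50, camera adjusted p = 0.036; adjusted p = 0.44 with an estimated correlation). Its call was lost without mutant replicates 1 or 3 in homeostasis or sibling replicate 2 at 3 h (0.051, 0.071 and 0.057), where 0, 0 and 8 were higher, and 0 to 2 were in every fit without another library except sibling replicates 1 and 3 at 3 h.

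Leukocyte markers were higher in mutants at 3 h as well, with 6 of 27 called (9 over the list alone; median 1.13, camera adjusted p = 1.1e-05; adjusted p = 0.51 with an estimated correlation), including csf1ra, a macrophage growth factor receptor gene, from 2.5 to 11.6 CPM (2.21, adjusted p = 0.013). That call was lost without mutant replicate 3 in homeostasis (0.061). The 6 became 1 to 3 without mutant replicates 1 or 2 at 3 h or any mutant replicate in homeostasis, and 11 without sibling replicate 2 at 3 h. Erythrocyte, muscle and all other remaining lists were not called in mutants, except G2 and M phase without mutant replicate 2 at 3 h (0.036). In all, 3634 genes passed, 1530 higher and 2104 lower. The total was 2360 (985 higher) without mutant replicate 3 at 3 h, 2334 and 2174 (786 and 751 higher) without mutant replicates 1 and 2 in homeostasis, and 6147 (2924 higher) without sibling replicate 2 at 3 h. In the fits without mutant replicate 2 at 3 h and replicate 3 in homeostasis 880 and 832 rose.

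**Figure D3:**
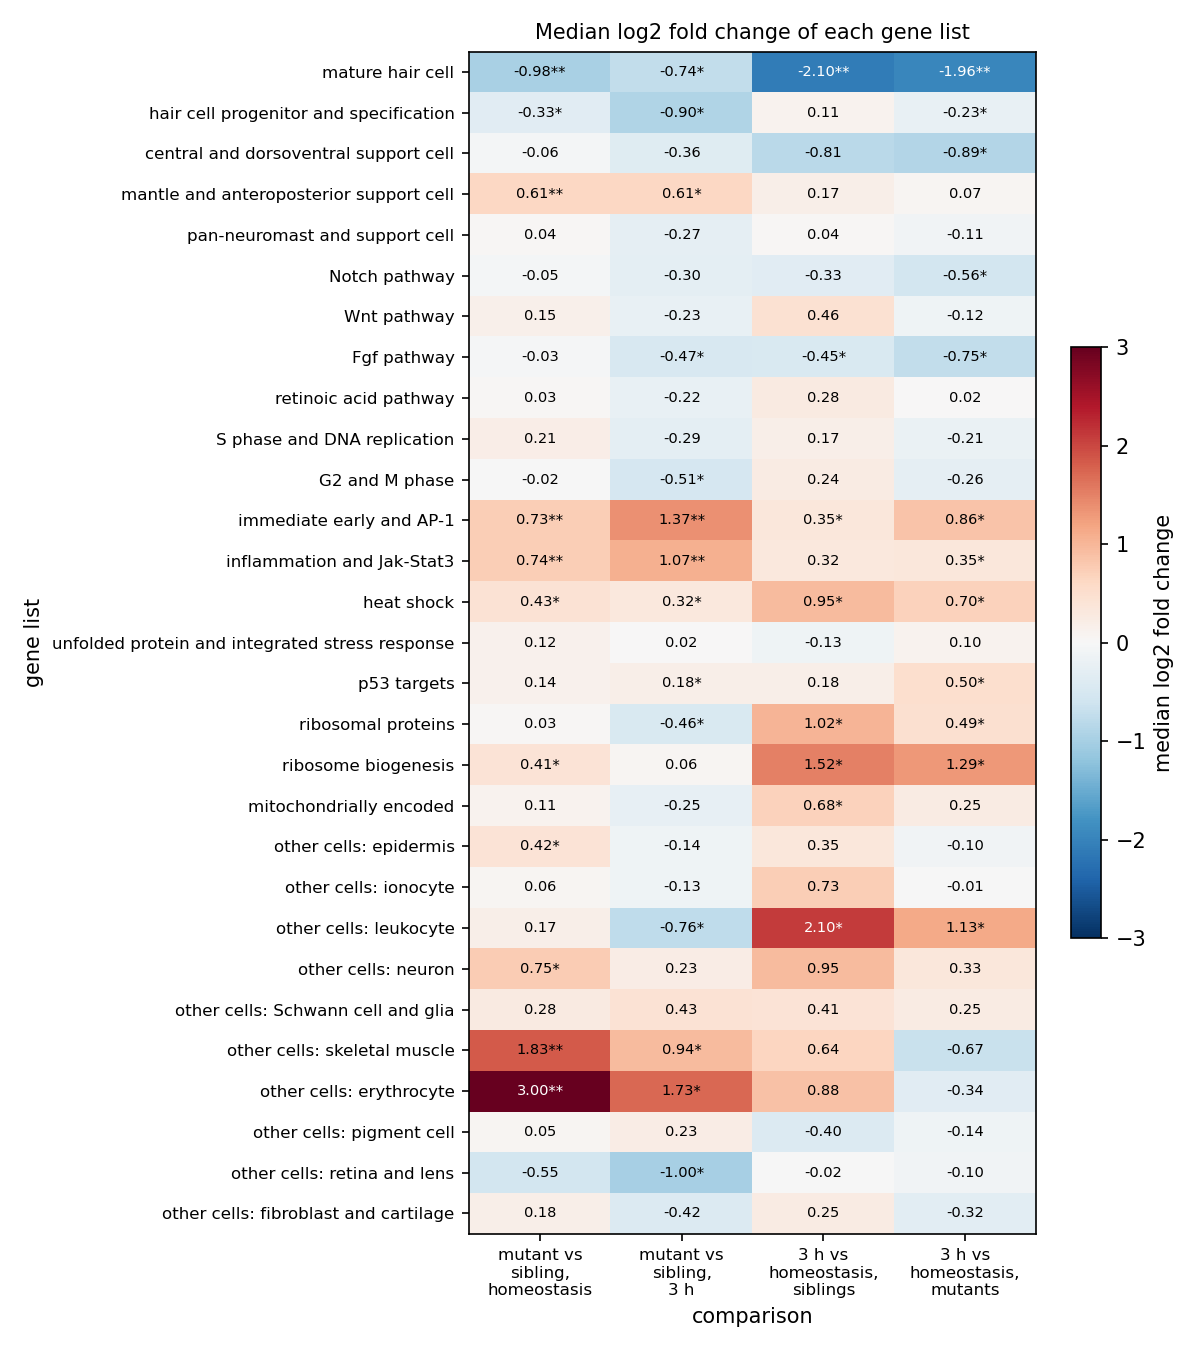
Median log2 fold change of the tested members of each of 29 gene lists in the 4 comparisons (* camera adjusted p under 0.05 with preset correlation, ** also with estimated correlation). Mature hair cell genes are lower in all 4 columns, from −2.1 to −0.74, and AP-1 genes are higher, from 0.35 to 1.37.

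Siblings and mutants shared much of the response to neomycin. Of the genes that rose, 992 were called in both, against 171.4 expected for independent lists, and of those that fell 1465 were, against 226.4; 11 were called in opposite directions. Across all tested genes the log2 fold changes of the 2 responses, which share no library, had a Pearson correlation of 0.671 and a Spearman correlation of 0.619.

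The interaction tested directly whether the responses differed. A difference passed for 23 genes, 22 of them with a higher response in mutants and 1 with a lower one. The clearest were PLEK2, PTGS2 (ENSDARG00000010276) and ACSBG2, an acyl-CoA synthetase gene, each with an adjusted p of 0.003. PLEK2 was at 10.6 ± 1.31 and 10.5 ± 3.08 CPM in siblings before and after neomycin and at 18.8 ± 1.13 and 175 ± 27 CPM in mutants (interaction 3.23 ± 0.32 SE). PTGS2 fell in siblings from 24.1 ± 7.41 to 5.8 ± 0.601 CPM and rose in mutants (3.5 ± 0.36). ACSBG2 was at 95.1 ± 2.43 and 19.3 ± 4.13 CPM in siblings and at 49.4 ± 4.79 and 54.8 ± 3.63 CPM in mutants (2.45 ± 0.26). These 3 were the only ones of the 12 named calls that held in each of the 12 fits that left 1 library out. The carbonic anhydrase gene ca4a had the lower response (−2.81, adjusted p = 0.047). No list had an interaction call with an estimated correlation (lowest adjusted p 0.29), though 11 lists had one with preset correlation. The count of 23 was between 3 and 7 without any 1 mutant library or any 1 sibling homeostasis library, 14 without sibling replicate 1 and 190 without sibling replicate 2 at 3 h. In simulated data of the same size, the interaction test recovered 26% of 4-fold and 1% of 2-fold differences, so most differences in response of such a size would not be called at this depth and number of libraries.

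**Figure D4:**
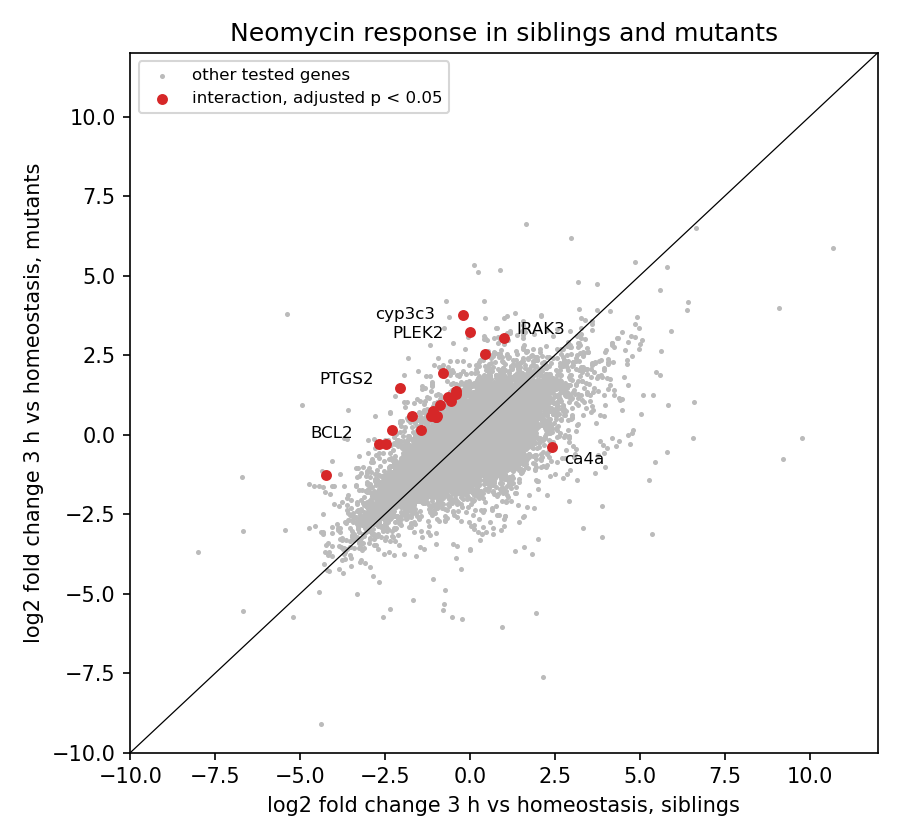
Log2 fold change from homeostasis to 3 h after neomycin for each tested gene, in siblings (horizontal) and mutants (vertical), with the line of equal change. The 23 genes with an interaction are in red, and 22 of them lie above the line.

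The last comparison set the mutant difference in homeostasis beside the sibling response to neomycin. Of 378 genes lower in mutants in homeostasis, 306 also fell after neomycin in siblings, against 40.7 expected for independent lists. These included GALNT9, OSBPL1A, barhl1a, LHX3 and PAX2 (ENSDARG00000028148). Of the genes higher in mutants, 185 also rose in siblings, against 45.6, among them FOSL1, and 7 went opposite ways. Both comparisons use the 3 sibling homeostasis libraries, so chance values are shared. In 20 simulations no group changed, so the 0 genes called in both cannot gauge the overlap. Their correlation of log2 fold changes was 0.498 (0.471 to 0.518) and covariance 0.127 (0.119 to 0.139). The observed correlation was 0.454 (Spearman 0.459), below the simulated one, and the observed covariance was 0.365, a difference of 0.238. With 3 control libraries the controls could not be split into parts of at least 2, and part of the excess may come from the shared controls.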

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

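The tests of library depth, of a mutant library under a sibling label, of a lower share of hair cells, of leukocytes and of dissociation stress were chosen only after the result was seen. The lists of gut, liver and pancreas genes and the second erythrocyte and muscle lists were also chosen after the data had been seen, but the bounds on them were set before their values were.

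The response to neomycin differed between mutants and siblings for 23 genes by the interaction test itself, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 1955 genes passed, and DESeq2 and voom called 335 and 379. The response, as the log2 fold change from homeostasis to 3 h, was higher in mutants for PLEK2 by 3.23, for PTGS2 (ENSDARG00000010276) by 3.50 and for ACSBG2 by 2.45. Each had an adjusted p of 0.003 and a call that held in all 12 fits that left 1 library out. ppp1r15b, which encodes a regulatory subunit of the phosphatase of eIF2alpha, was at 15 and 8.75 CPM in siblings before and after neomycin and at 12.7 and 48.1 CPM in mutants (2.72, adjusted p = 0.01). F2RL1 (ENSDARG00000077540) had 1.77 (0.01). The calls of both were lost without mutant replicate 1 at 3 h (both 0.053) or mutant replicate 3 in homeostasis (0.056 and 0.064), and that of ppp1r15b without mutant replicate 3 at 3 h (0.051). BCL2 (2.38), an inhibitor of apoptosis, IRAK3 (2.04), hap1 (2.17), cyp3c3 (3.97), RHPN2 (1.55) and the co-chaperone gene BAG3 (1.83) also had a higher response in mutants, with adjusted p from 0.015 to 0.047. The carbonic anhydrase gene ca4a had a lower one (−2.81). The call of BCL2 was lost without mutant replicates 1 or 3 at 3 h, or mutant replicates 2 or 3 or sibling replicates 1 or 2 in homeostasis (0.051 to 0.09). Those of IRAK3 and hap1 were lost without mutant replicates 1 or 3 at 3 h, or any mutant replicate or sibling replicates 1 or 3 in homeostasis (0.051 to 0.12), and that of IRAK3 also without mutant replicate 2 at 3 h (0.066). Those of cyp3c3, RHPN2, ca4a and BAG3 held without sibling replicate 2 at 3 h and were lost without any other library (0.061 to 0.18), apart from cyp3c3 without mutant replicate 1 and BAG3 without sibling replicate 3 at 3 h.

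With preset correlation, 11 lists had an interaction call, and none did with an estimated correlation (lowest adjusted p 0.29). Mature hair cell genes (median 0.21, adjusted p = 0.0026), AP-1 genes (0.38, 0.0022) and inflammation genes (0.09, 0.0088) had a higher response in mutants. A lower response was called for Wnt (−0.59, 0.0025), S phase (−0.52, 0.0022), G2 and M phase (−0.49, 0.0088), ribosomal protein (−0.52, 2.7e-06), ribosome biogenesis (−0.32, 0.0088), leukocyte (−1.01, 0.0012), skeletal muscle (−0.57, 0.0012) and erythrocyte genes (−1.32, 0.0011). The median of all tested genes was −0.14. The hair cell median was 0.03 and 0.07 without mutant replicate 2 and sibling replicate 3 at 3 h, and 0.34 and 0.44 without sibling replicates 1 and 2 at 3 h. That of AP-1 was 0.58 without sibling replicate 2 at 3 h and 0.22 without sibling replicate 1 in homeostasis. That of inflammation was 0.04 and 0.2 without mutant replicates 1 and 3 at 3 h, 0.33 and 0.22 without sibling replicates 1 and 2 at 3 h, and 0.2 without sibling replicate 1 in homeostasis. The medians of Wnt, G2 and M phase, ribosomal protein, ribosome biogenesis, leukocyte and muscle genes were −0.39, −0.15, −0.1, −0.11, −0.5 and −0.25 without sibling replicate 2 at 3 h. The G2 and M phase median was −0.77 without mutant replicate 2 at 3 h, that of ribosome biogenesis −0.16 without sibling replicate 2 in homeostasis, and that of muscle −0.25, −1.12 and −0.91 without mutant replicates 1 and 3 at 3 h and sibling replicate 2 in homeostasis. Without sibling replicate 2 at 3 h, the calls of G2 and M phase (0.15), inflammation (0.067), ribosomal protein (0.15), ribosome biogenesis (0.12) and leukocyte genes (0.067) were lost. The hair cell call was lost without mutant replicate 2 at 3 h (0.067), that of AP-1 without sibling replicate 1 in homeostasis (0.16) and that of inflammation without mutant replicate 3 in homeostasis (0.12). That of G2 and M phase was lost without mutant replicate 3 at 3 h (0.082) or mutant or sibling replicate 1 in homeostasis (0.088 and 0.11), and that of ribosome biogenesis without mutant replicate 1 at 3 h (0.085), mutant replicate 3 (0.076) or sibling replicate 2 (0.26) in homeostasis.

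Sibling replicate 2 at 3 h stood apart from replicates 1 and 3. Its depth was the highest of the 12 libraries (30354161 counts, 30.4 M), and its 289 CPM of ISL1 lay far above the 1.49 CPM of the highest mutant library, which argued against low depth and against a mutant library under a sibling label. Cells of gut, liver or pancreas in this library may account for it. Over 67 genes of the 4 added lists its log2 CPM exceeded the mean of replicates 1 and 3 by a median of 0.99 ± 0.17 SE, within its error of the bound of 1 that was set beforehand, so the explanation stayed open: the liver list reached 1.51 ± 0.24 with 14 of 18 genes above both replicates (apoa2 at 2620 CPM against 289 and 1100), whereas exocrine pancreas (1.07 ± 0.16) had 2 of 14, with prss1 at 2170 CPM in replicate 1, 1990 in replicate 2 and 337 in replicate 3. Gut (0.52 ± 0.37) had 11 of 24 and endocrine genes (0.85 ± 0.53) 7 of 11. The mCherry sort should remove such cells. Siblings in homeostasis still held at least 1 CPM of 17 liver, 14 exocrine, 11 gut and 6 endocrine genes. No biological explanation was tested.

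Blood and muscle genes were higher in mutants in homeostasis. A lower share of hair cells would raise markers of all other cells alike, and the erythrocyte median exceeded the pan-neuromast median by 2.96 ± 0.38 SE, which argued against it for the blood genes. Erythrocytes and muscle fragments among the sorted cells may account for the rise. Second lists, sharing no gene with the others, had medians of 1.22 (19 of 22 above 0) and 1.72 (18 of 23). Both passed the bound of 1 set beforehand, but muscle had 0.95 without mutant replicate 3 in homeostasis. The most abundant erythrocyte genes, hbae1.3 and hbae3, went from 35.2 and 86.7 to 476 and 423 CPM. The muscle genes ckma and actc1b went from 37.3 and 6.05 to 73.9 and 61.5 CPM. The mCherry sort should keep such levels low. Of the second lists, 21 and 10 genes had at least 1 CPM in sibling cells before neomycin, and a difference between the genotypes in these tissues stayed open and untested.

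AP-1 and inflammation genes were higher in mutants in both states. In homeostasis, a lower share of hair cells stayed open. The median of all 77 tested genes of both lists was 0.74, 0.7 above pan-neuromast, but mantle genes had 0.57 to 0.68 with 1 library left out. Against leukocytes among the sorted cells, the leukocyte list was at −0.76 at 3 h, 2.13 ± 0.27 SE below the AP-1 list, with its most abundant genes MFAP4 (ENSDARG00000088745) at 62.8 CPM in mutants and 148 in siblings and LCP1 at 78.8 and 105 CPM. Without sibling replicate 2 at 3 h the leukocyte median was −0.25. Stress of dissociation and sorting may account for part of the pattern and stayed open, since the heat shock list had a median of 0.43 in homeostasis (0.18 without sibling replicate 1 and 0.26 without mutant replicate 3) but no call with an estimated correlation (adjusted p = 0.44), and a response of the mutant cells themselves was not tested.

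Other splits of the libraries were tried for each count. For the 4 pairwise comparisons 6 libraries give 10 splits, too few for a share under 0.05; the real splits gave 785, 2151, 4831 and 3634 genes, and the highest other split gave 0 in each. Among the 4 splits that part all 3 pairs of same-numbered libraries at 3 h, the highest other count was also 0. For the interaction, 4 of 60 drawn from 200 assignments of genotype within treatment, the real one included, gave at least 23 genes. The highest other gave 3384. Such assignments exchange the genotypes in 1 treatment, wholly or in part, and so turn the genotype differences into an interaction. They are no measure of chance alone, so this count could neither exclude chance nor speak for it.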

How the results depend on the processing

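The fits that leave out 1 library each, the block, the other scalings, tests, filters and thresholds were planned, and only the fit of the block with the 6 libraries at 3 h and the fit without both libraries numbered 2 at 3 h were chosen after seeing the data. No call that the naming rule gives reversed its direction in any of them, and no called list fixed beforehand had a median that changed sign with the block, the other scalings or 1 library left out. Lists that were not called did, such as the progenitor list in siblings, whose median went from 0.11 to −0.16 without sibling replicate 2 at 3 h. The cause of the changes below was not tested, except that a stricter threshold calls fewer genes by construction.

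With the replicate number as a block, 1210, 2789, 5336, 4166 and 16 genes passed in place of 785 and 2151 (mutant against sibling in homeostasis and at 3 h), 4831 and 3634 (3 h against homeostasis in siblings and mutants) and 23 (interaction). The block kept 57 of 57, 85 of 85, 101 of 105, 100 of 101 and 11 of 12 calls that the naming rule gives. It changed no list call except that of Fgf (0.057) and of neurons (0.045) at 3 h. Outside the comparison at 3 h, same-numbered libraries had correlations of 0.212, 0.049 and −0.059 (homeostasis), 0.262, −0.043 and 0.08 (siblings) and 0.046, 0.227 and 0.172 (mutants). With the block and only the 6 libraries at 3 h, 2346 genes passed, and without both libraries numbered 2 at 3 h 2823.

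With only the 6 libraries compared, 2217, 625, 2287 and 6150 genes passed (885, 447, 863 and 2970 higher). Of these calls, 46 of 85 held at 3 h and 71 of 105 in siblings. DESeq2 called 1796, 3515 and 335 genes in homeostasis, at 3 h and in the interaction. Voom, which gave sibling replicate 2 at 3 h a weight of 0.108, called 3174, 4450 and 379 in these and 7712 in mutants. At an adjusted p under 0.01, 224, 712, 2532, 1810 and 3 genes passed (148, 478, 1100, 648 and 3 higher). Upper-quartile scaling left 11 genes in the interaction. Leaving out 1 library gave 295 to 2079, 896 to 2964, 3060 to 5367, 2174 to 6147 and 3 to 190 genes. The interaction's highest count and those in homeostasis, at 3 h and in mutants came without sibling replicate 2 at 3 h.

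With an estimated correlation, 6, 2, 1, 1 and 0 lists were called in place of 11, 14, 8, 12 and 11. With fry, 8 were called at 3 h and 1 in the interaction. The correlation of both responses to neomycin was 0.671 over all genes, 0.824 over genes called in either, 0.664 with the block and 0.614 without sibling replicate 2 at 3 h. Without that library the mutant difference in homeostasis and the sibling response had a correlation of 0.467.

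All other totals of called genes and of called lists stayed within 1.5 times those reported, while counts within single lists moved more. Scaling moved the share of higher calls by at most 10 points, and the median of all genes at 3 h between mutants and siblings from −0.14 to −0.11 or −0.17. The planned test of calls on the chromosome of isl1a was not run, because too few genes had a position. Depth and 3 libraries per group limit small effects: in simulated data 2-fold changes were recovered in 11% of genes in homeostasis and 1% in the interaction.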

Other observations

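All lists and genes of this part were chosen after the data had been seen, and all its tests were run only then. Transcripts of vessels and of the response to low oxygen were higher in mutants in homeostasis. Of 13 endothelium genes 5 rose and none fell (8 over the list alone; median 1.32, camera adjusted p = 6.7e-13, 0.019 with an estimated correlation), or 3 without sibling replicate 3 in homeostasis. The tight junction gene CLDN5 (ENSDARG00000014059) went from 2.79 to 24.5 CPM (3.13, adjusted p = 0.0011), and the transcription factor gene SOX7 from 4.25 to 23.7 CPM (2.48, 0.0016). The more abundant members ESAM and kdrl went from 63 and 13.5 to 69.3 and 27.8 CPM and were not called. Siblings held at least 1 CPM of 11 of the 13. At 3 h 5 were higher as well (median 0.56, camera adjusted p = 0.00013; adjusted p = 0.3 with an estimated correlation), or 3 without mutant replicate 3 at 3 h, and the median was 1.01 without sibling replicate 1 at 3 h. Of 21 hypoxia targets, 2 of them in another list, 2 rose (median 0.36, camera adjusted p = 0.00056, 0.041 with an estimated correlation), or 0 or 1 without any 1 mutant library or sibling replicate 2 in homeostasis, and the median was 0.55 and 0.23 without sibling replicates 1 and 2 in homeostasis. Of the same list 6 were higher at 3 h (0.43, 0.00073; adjusted p = 0.16 with an estimated correlation), or 3 without mutant replicates 1 or 2 or sibling replicate 3 at 3 h, with a median of 0.73 without sibling replicate 1 at 3 h. The single genes that led to that list were left out of it. Among them both ADM genes, which encode the vasoactive peptide adrenomedullin, rose in homeostasis from 16.2 to 269 (ENSDARG00000069027) and from 7.18 to 102 CPM (ENSDARG00000015263), ANKRD37 from 1.06 to 10.9, P4HA1 from 4.9 to 23.2, EGLN3 from 1.97 to 9.72 and PFKFB3 from 5.63 to 23.6 CPM, with adjusted p from 0.00045 to 0.0099.

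PKLR was at 159 CPM in siblings and 4.86 CPM in mutants at 3 h (−5.03, adjusted p = 8e-04). Of 14 exocrine pancreas genes, all with at least 1 CPM in siblings, none was called in homeostasis, with a median of −1.48 (camera adjusted p = 0.00021; adjusted p = 0.43 with an estimated correlation), or −0.49 without sibling replicate 2 in homeostasis. At 3 h 7 were lower (all 14 over the list alone; median −2.72, camera adjusted p = 8.7e-08; adjusted p = 0.35 with an estimated correlation), or 1, 0, 4 and 11 without mutant replicates 2 and 3 and sibling replicates 1 and 3 at 3 h. The elastase gene ela2l was at 1550 CPM in siblings and 99.5 in mutants. Of 18 liver genes 1 rose and 2 fell in homeostasis (median −0.99, camera adjusted p = 0.00021; adjusted p = 0.43 with an estimated correlation), and 5 were lower at 3 h (−0.93, 0.025; 0.5 with an estimated correlation). At most 1 was lower in 9 of the 12 fits that left 1 library out in homeostasis, 4 were lower without sibling replicates 1 or 2 at 3 h there, and 2, 3 and 3 were lower at 3 h without mutant replicates 1, 2 and 3. The median in homeostasis was −1.71 and −0.53 without mutant replicates 2 and 3 in homeostasis, and that at 3 h −1.46 and −0.36 without mutant and sibling replicate 2 at 3 h. The most abundant of them, apoa2 and fetub, were at 777 and 636 CPM in siblings and 273 and 66.6 CPM in mutants in homeostasis.

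The second erythrocyte list had 9 of 22 genes higher in mutants in homeostasis (camera adjusted p = 8.7e-14, 0.019 with an estimated correlation), or 4 and 5 without mutant replicate 1 and sibling replicate 3, and 1 at 3 h (0.015; adjusted p = 0.35 with an estimated correlation). The second muscle list had 3 of 23 higher in homeostasis (9.4e-07, 0.041 with an estimated correlation), or 0 or 1 without any 1 homeostasis library, and none at 3 h (0.15). Glycolysis enzymes were not called in homeostasis (0.76), while 4 of 25 were higher and 1 lower at 3 h (median 0.43, camera adjusted p = 0.031; adjusted p = 0.35 with an estimated correlation), or 2 and 1 without mutant replicates 2 or 3 (medians 0.27 and 0.26) and 9 and 1 without sibling replicate 2 at 3 h. Gut (0.097 and 0.15) and endocrine (0.49 and 0.24) lists were not called in either state. In the responses to neomycin none of the 9 lists was called (lowest adjusted p 0.18 in siblings and 0.46 in mutants). The interaction was called for exocrine pancreas (0.0013), endothelium (0.038), second erythrocyte (9.7e-05), second muscle (0.0034) and glycolysis lists (0.036), and for none of them with an estimated correlation (lowest adjusted p 0.36). The glycolysis median of 0.16 was −0.02 without sibling replicate 3 at 3 h or in homeostasis, 0.07 without mutant replicate 2 and 0.33 without sibling replicate 2 at 3 h.

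Sibling replicate 2 at 3 h also held hormone transcripts. SST, the somatostatin gene, was at 150 CPM against at most 0.631 in any other library, ins at 13.2 against 0.533 and gcga at 21.4 against 4.3 CPM.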
